A study of Mus musculus with 2 samples.

How the data were processed

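H3K4me1, the monomethylated form of lysine 4 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in kidneys of mouse embryos of the B6NCrl strain at embryonic day 15.5. The 2 samples were biological replicates of 1 group, pools of kidneys from 78 embryos (replicate 1) and from 62 embryos (replicate 2). Per the labels both pools held males and females, with no ratio given, and the libraries had a size range of 300 to 500 bp. A control experiment that the labels name was not analysed here. The notes deposited with the samples list 2 further files behind the calls of replicate 1 and 1 behind those of replicate 2, without their roles, so whether both replicates' peaks were called in the same way is not known.

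The authors aligned the reads to mm10 and called peaks. The 4 deposited lists hold the peaks of replicate 1, of replicate 2, of both replicates' alignments pooled, and a list of replicated peaks. The caller, its version, its threshold and the rule that makes a peak replicated are not given in the sources used here. Each peak has an enrichment, a linear ratio as the authors' caller wrote it (relative to what is not given in the sources used here), and the deposited −log10 p and −log10 q of the same caller. Every score per peak is therefore the authors', and the scores of separately called lists were compared as ranks. The exception is alternatives that applied the same minimum score to each list. The lists hold no read counts, so the depth of each replicate is unknown and no interval that needs it is given. The number and the width of called peaks can change with depth, which limits every comparison of covered length between replicates. All replicated peaks were found as lines of the pooled list, and 74.6% of them overlapped a peak in each replicate by at least 50% of either peak.

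Chromosomes 1 to 19, X and Y were used, which left out 3, 1, 2 and 0 peaks on other sequences from the lists of replicate 1, replicate 2, the pooled and the replicated peaks. Genes were the protein-coding genes of GENCODE mouse release 21 on GRCm38 (mm10), and their TSS (transcription start site) was the annotated 5′ end of the gene. For the division of the genome and for the distance of peaks from TSSs, the starts of all annotated transcripts of any gene type were used. Sequence came from the RefSeq assembly of the same build. Coordinates are 1-based and include both ends. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyfaidx 0.9.0.4, matplotlib 3.10.9 and samtools 1.23.1 were used.

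Replicate overlap was the share of a replicate's peaks that overlapped the other's by at least 1 bp, and the shared length over the union. It was compared with 1000 random circular shifts of the other replicate's peaks within each chromosome (one-sided permutation test, smallest possible p 0.001). Shifted peaks can fall in assembly gaps, which lowers the shifted overlap. Spearman's rho of enrichment was taken across replicated peaks, using the strongest overlapping peak of each replicate. Merged replicated peaks were divided into promoter (within 1 kb of a TSS), exon, intron and intergenic length and compared with 1000 circular shifts (two-sided permutation test, smallest possible p 0.002). For the TSS profile, the share of genes with a replicated peak was computed in steps of 100 bp to 10 kb on each side, with 95% intervals from 1000 bootstrap resamples of genes. TSSs were called CpG-rich when the observed over expected CpG ratio within 500 bp on each side was 0.6 or more.

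For gene lists, the share of the TSS ±50 kb window covered by replicated peaks was computed for each gene. The median of each of 18 lists was compared with 10000 random lists of the same size, matched on quintile of gene length and quintile of the number of protein-coding TSSs in the window (two-sided permutation test, smallest possible p 0.0002). Benjamini-Hochberg adjustment was over the 18 lists, with a threshold of 0.05. The lists covered nephron progenitor, early nephron, podocyte, ureteric bud and collecting duct, renal stroma, proximal tubule, loop of Henle and distal tubule, endothelium, macrophage, erythroid, adrenal cortex, gonad and germ line, hepatocyte, neuron, striated muscle, epidermis, housekeeping and olfactory receptor genes. A gene of 2 lists counted in both. Members were matched to the annotation by symbol. Ahsp was not matched, which left 15 of 16 erythroid genes, and every member of the other lists was matched. The random lists for the olfactory receptors could themselves hold olfactory receptor genes. For the replicate difference, replicate 1 was reduced to its 173543 strongest peaks by −log10 p, the number of all replicate 2 peaks. The median of replicate 1 minus replicate 2 coverage was tested in the same way. Hox genes were described by the share of the gene body ±2 kb covered, with no test.

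For motifs, 500 bp around the middle of each replicated peak over 2.5 kb from any TSS were compared with 500 bp regions 5 kb to each side that overlapped no peak of any list. The share of regions with a match on either strand to each of 19 consensus sequences was compared by chromosome with a two-sided sign-flip permutation test (100000 resamples, smallest possible p 1e-05, Benjamini-Hochberg over the motifs). The shares given are unweighted means over chromosomes, and a ratio is the mean share of peaks over that of flanks. Several consensus sequences are short or tolerate mismatches, so a match is not a bound factor. A first computation had also required flanks to lie over 2.5 kb from any TSS. That condition was not part of the plan, was removed from the reported values, and is kept as an alternative.

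The comparisons, tests, gene lists, motifs and most alternatives were fixed before the data were examined. The rule for named genes, fixed at the same time, took from each list except the olfactory receptors the 3 members with the highest and the 1 member with the lowest window coverage. It also took any Hox gene, the 10 peaks with the highest enrichment, the 10 domains (replicated peaks merged when within 3 kb) with most covered length, and the 2 members with the largest replicate difference in each direction for lists that passed. Alternatives varied the peak threshold (−log10 q of at least 5, enrichment of at least 4), the peak list, each replicate alone, the overlap, the promoter distance (2.5 kb), the TSS choice, the window (20 kb, 100 kb, gene body ±5 kb), the measure, the matching, the summary, the GC content (10 bins) and the motif region (200 bp). Alternatives chosen after seeing the data were peaks with at least 50% overlap in both replicates, matching on chromosome class, random genes drawn outside the list, equal covered length and matching on coverage for the replicate difference, flanks away from TSSs, and the ratio of each motif against up to 299 other orders of its own letters with as many CG. The number of orders was raised after a first, smaller run, in which 0 of 19 motifs passed.

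The tests were tried on simulated data, with p not adjusted for multiple testing. With no effect, 6.1% of 1000 random lists of 20 genes gave a p under 0.05. That number of lists was raised after a first, smaller run had given a higher share. With the coverage of a list's genes multiplied by 2 and by 3, 54.3% and 85% of lists did. For replicate overlap, 5% of 20 simulated pairs without shared peaks and 100% of 20 pairs with 30% shared peaks gave a p under 0.05. For motifs, 0% of 19 did without a planted motif and 100% with the motif planted in 2% of peak regions. The simulated peaks and flanks had the same even base content, whereas real peaks were richer in GC than flanks (48.7% against 44.3%). The 0% therefore does not cover calls that arise from base content.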

Results

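H3K4me1, a histone mark of enhancers and of the flanks of promoters, was mapped by ChIP-seq in mouse kidney at embryonic day 15.5, when nephron progenitors, the branching ureteric bud, stroma, vessels and young nephrons are present together. The 2 samples were biological replicates of 1 group, pools of kidneys from 78 embryos (replicate 1) and 62 embryos (replicate 2) of both sexes. With 1 group there was no contrast between conditions. The comparisons concerned how alike the maps of the pools were, where the mark lay relative to genes, which lineages' genes lay in covered neighbourhoods, and which motifs the covered regions held. The deposited data were peak lists without read counts, so the depth of each replicate was unknown. Peaks and genes are not independent replicates, and each p below comes from moving peaks, redrawing genes or flipping chromosomes, not from the 2 pools. Positions refer to mm10.

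The replicated peaks, 151594 in number, covered 124 Mb or 4.56% of the genome. Their median width was 570 bp, and the median of the authors' enrichment was 3.12. Replicate 1 held 230492 peaks (120 Mb, 4.41% of the genome, median width 333 bp) and replicate 2 held 173543 (91.3 Mb, 3.35%, 349 bp). The pooled list held 231465 peaks over 145 Mb. The strongest replicated peak, with an enrichment of 11.8, lay on chromosome 8 from 120176318 to 120179039, within 1 kb of a TSS at Fam92b. The second, with an enrichment of 11.3, lay on chromosome 11 from 98958754 to 98971920 in an intron of Rara, which encodes a retinoic acid receptor. The next peaks by enrichment lay in introns of Ahdc1 (11.2), Cxxc5 (11.1) and Ctif (10.8, with Smad7 as the gene of nearest TSS), and a peak in Sema3f, a secreted guidance cue, reached 10.5. Of the 10 strongest peaks, those in Iffo2, Ncor2 and Cmip were intronic as well, with enrichments of 10.3 each, and the peak at Zbtb48 (10.8) lay within 1 kb of a TSS.

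When peaks within 3 kb were merged, 64463 domains resulted, of which 289 held over 20 kb of covered length against a median of 1.06 kb. The domain with most covered length (96.5 kb in 42 peaks) lay in Msi2, which encodes an RNA-binding protein, on chromosome 11 from 88520938 to 88641475, and the replicates covered 71.6% ± 7.14 of it (SD, n = 2). The next lay over Gse1 on chromosome 8 (77.2 kb) and over the Hoxc cluster on chromosome 15 from 102949706 to 103043095 (74.2 kb, Hoxc4 to Hoxc11). Tead1, which encodes a DNA-binding partner of the Hippo pathway, held 66.9 kb on chromosome 7, and the replicates covered 70.9% ± 1.89 of that domain (SD, n = 2). The anterior part of the Hoxa cluster (Hoxa1 to Hoxa7) held 58.5 kb on chromosome 6, covered to 74.8% ± 0.270 by the replicates (SD, n = 2). Ncor2, a corepressor of nuclear receptors, was among the 10 strongest peaks and the 10 largest domains (59.4 kb).

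Most strong peaks of each tissue pool overlapped a peak of the other pool. Of replicate 2 peaks, 82.5% overlapped a replicate 1 peak, against 8.60% ± 0.389 (SD of 1000 shifts) when the peaks were shifted along the chromosomes. Of replicate 1 peaks, 58.8% overlapped a replicate 2 peak, against 6.51% ± 0.293. Shared length was 51.2% of the union, against 2.25% ± 0.133. Each of the 3 values exceeded every shift (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Overlap rose with the strength of the peak. In replicate 1 it went from 28.7% in the weakest decile by −log10 p to 99.4% in the strongest, and in replicate 2 from 64.7% to 99.9%. Each decile was compared with all peaks of the other replicate. With both lists cut at −log10 q of at least 5, 53.1% of 83857 replicate 1 peaks and 84.4% of 53494 replicate 2 peaks overlapped the other list. Strong peaks were also wider (median 1239 bp in the strongest decile of replicate 1 and 222 bp in the weakest), and a wide peak meets another more often by chance. Across 114057 replicated peaks with a peak in both replicates, enrichment ranks correlated at a Spearman's rho of 0.558, which ranged from 0.378 to 0.611 over 20 chromosomes. Of the pooled peaks, 12.7% overlapped neither replicate's own list.

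**Figure D1:**
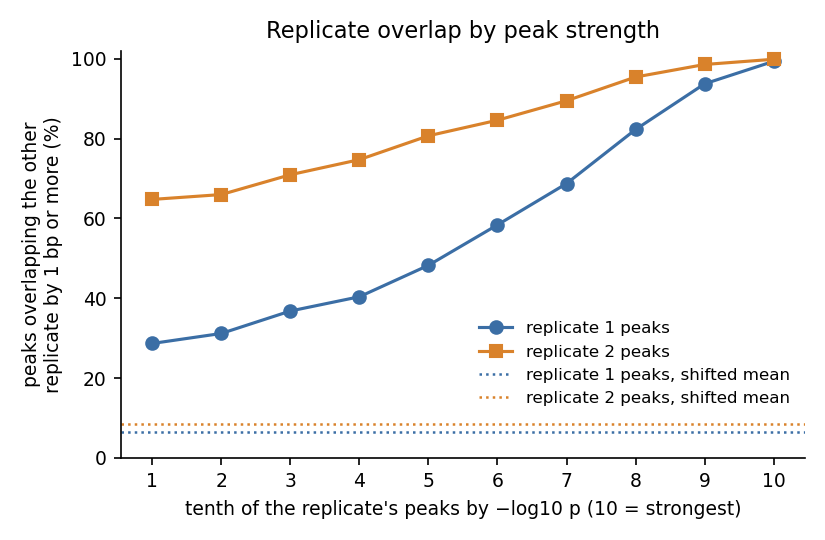
Share of each replicate's peaks (y axis, %) that overlap a peak of the other replicate by at least 1 bp, by decile of the authors' −log10 p within the replicate (x axis, 10 is the strongest); points are deciles of 1 replicate and dotted lines are the means over 1000 circular shifts of all peaks. Overlap reaches 99.4% and 99.9% in the strongest deciles, and the weakest deciles, at 28.7% and 64.7%, lie above the shifted means of 6.51% and 8.60%.

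Promoters and introns held more of the mark than shifted peaks, and the space between genes held less. Of replicated peak length, 20.9% lay within 1 kb of a TSS, 3.34 times the share of shifted peaks (6.26% ± 0.215, SD of 1000 shifts). Exons took 4.86% (1.45 times), introns 50.2% (1.27 times) and intergenic sequence 24.0% (0.473 times). All 4 differences passed (two-sided permutation test, p = 0.002, the smallest that 1000 shifts can give). In absolute terms, introns and intergenic sequence together held most of the covered length. Shifted peaks can fall in assembly gaps, which count as intergenic, so the shifted shares are approximate.

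Around TSSs the mark formed a peak on each side with a dip at the start site. A replicated peak covered the TSS of 20.4% of 21911 protein-coding genes, 40.7% at +1000 bp and 32.4% at −500 bp in gene orientation. The difference between the highest position and the TSS was 20.3 percentage points (95% bootstrap interval over genes 19.5 to 21). In the replicates, coverage was 17.2% ± 4.71 at the TSS and 35.7% ± 2.77 at +1000 bp (SD, n = 2), so the dip exceeded the spread between replicates. The dip was a feature of the 10062 CpG-rich TSSs, of which 16.7% were covered at the TSS and 65.9% at +1100 bp. At the 11842 CpG-poor TSSs, coverage was 23.6% at the TSS and 24.2% at its highest, 100 bp downstream. At the TSS itself CpG-rich genes were covered less often than CpG-poor genes, by −6.85 percentage points (95% bootstrap interval −7.92 to −5.81).

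The gene lists differed in the same profile. Housekeeping genes, of which 77.3% had a CpG-rich TSS, were covered at 13.6% of TSSs and 77.3% at +1500 bp (11.4% ± 3.21 and 72.7% ± 12.9 in the replicates, SD, n = 2), a difference of 63.6 points (bootstrap interval 36.4 to 86.4). Endothelial genes, of which 20% had a CpG-rich TSS, had no dip, with 70% covered at the TSS as at the highest position (65% ± 14.1 at both in the replicates, SD, n = 2). Nephron progenitor genes were covered at 65% of TSSs and 80% at +300 bp, a difference of 15 points whose interval (−5 to 35) included 0. Their coverage differed widely between the replicates, with 60% of TSSs in replicate 1 and 30% in replicate 2 (45% ± 21.2, SD, n = 2) and 75% and 45% at +300 bp (60% ± 21.2, SD, n = 2). Early nephron genes went from 55.6% to 88.9% at +900 bp (interval of the difference 5.56 to 55.6), and from 33.3% ± 7.86 to 69.4% ± 3.93 in the replicates (SD, n = 2). With 14 to 22 genes in each list other than the olfactory receptors, these profiles are coarse, and the highest position was chosen after the profile was seen.

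**Figure D2:**
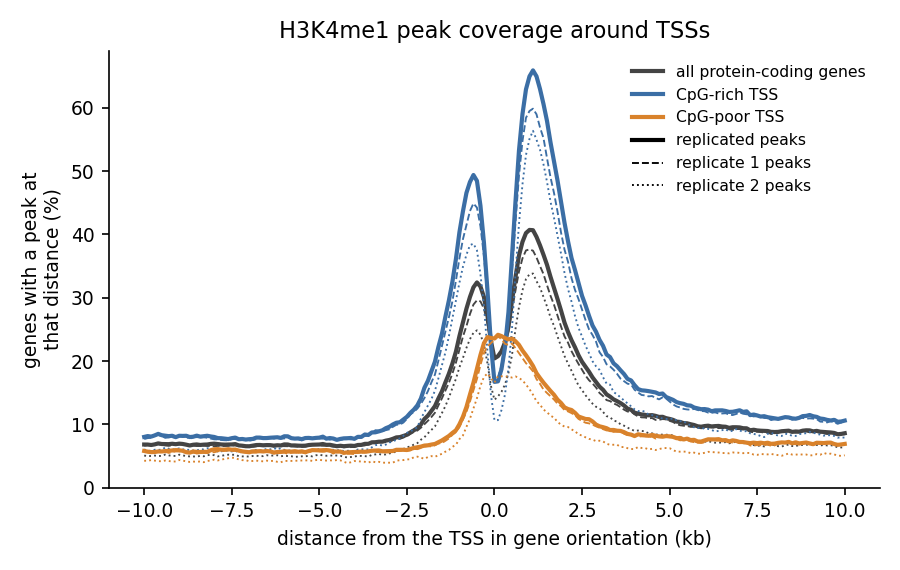
Share of protein-coding genes (y axis, %) with an H3K4me1 peak at each distance from the TSS in gene orientation (x axis, kb), for all genes, CpG-rich and CpG-poor TSSs; thick lines are replicated peaks, dashed lines replicate 1 and dotted lines replicate 2. CpG-rich TSSs dip to 16.7% at the start site between shoulders of 49.4% and 65.9%, and CpG-poor TSSs peak at 24.2%.

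Genes of nephron progenitors, early nephrons, the ureteric bud and the renal stroma lay in neighbourhoods with more H3K4me1 coverage than matched random genes. For the 20 nephron progenitor genes the median covered share of the TSS ±50 kb window was 17% (14.3% ± 3.02 in the replicates, SD, n = 2), against 4.21% in random lists matched on gene length and gene density. The 18 early nephron genes had a median of 16.0% (13.6% ± 2.86, SD, n = 2) against 3.65%. The 21 genes of the ureteric bud and collecting duct had 15.7% (13.9% ± 3.23, SD, n = 2) against 4.23%, and the 20 renal stroma genes 13.0% (10.5% ± 1.90, SD, n = 2) against 4.70%. Adjusted p was 0.0012, 0.0012, 0.0018 and 0.0101 (two-sided permutation test over 10000 random lists, Benjamini-Hochberg over 18 lists). These 4 lists passed in each replicate alone. Random lists were drawn across the genome, whereas some listed genes are neighbours with largely the same window, such as Hoxa10 and Hoxa11. The test does not allow for this, which can make p too small. The median over all protein-coding genes was 5.72%, and 17.9% of genes had no covered base in the window.

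Within the nephron progenitor list, 16 of 20 genes lay above the random median of the list and 10 in the top 10% of genes of similar length and gene density. Pax2, a transcription factor needed for kidney formation, had 42.4% of its window covered (35.2% ± 5.44, SD, n = 2) by 38 peaks on chromosome 19, the strongest of them 35.8 kb upstream of the TSS (44719225 to 44721245, outside protein-coding genes). Hoxd11 (45.9%, 39.7% ± 3.25) and Hoxa10 (41.4%, 37.6% ± 5.54, both SD, n = 2) lay within Hox clusters, whose genes share their windows. Cited1, a marker of uncommitted progenitors, was lowest at 1.03% and lies on the X chromosome, where peaks were few. All 18 early nephron genes lay above the random median of their list. Notch2, a receptor that patterns the proximal nephron, had 47.3% (44.2% ± 2.09), Lfng, which modifies Notch receptors, 42.1% (36.2% ± 8.33), and Wnt4, which drives the conversion of progenitors to epithelium, 31.4% (26.5% ± 3.42, all SD, n = 2). The strongest peak of the Wnt4 window lay in an intron of Wnt4, on chromosome 4 from 137281669 to 137283936. Dkk1 was lowest at 3.78%.

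In the ureteric bud and collecting duct list, 19 of 21 genes lay above the random median. Hoxb7 had the highest share of any named list member, 71% (66.1% ± 3.35, SD, n = 2), with the Hoxb cluster in its window. Wnt11, a signal of the ureteric tip, had 39.1% (31.1% ± 6.63) and Cdh1, which encodes E-cadherin, 29.0% (21.1% ± 5.69, both SD, n = 2), with its strongest peak 0.304 kb from the TSS. Calb1 was lowest at 0.763%. In the renal stroma list, 16 of 20 genes lay above the random median. Pbx1, a Hox cofactor, led with 38.3% (34.8% ± 2.01, SD, n = 2), and its strongest peak lay in its own intron on chromosome 1 from 168380050 to 168387553. Pdgfrb, a receptor of pericytes and mesangium, had 30.1% (24.8% ± 4.74) and Sfrp1, a Wnt inhibitor, 26.4% (21.9% ± 4.90, both SD, n = 2), while Rarb had no replicated peak in its window. The renal stroma call was lost by number of peaks (median 14.5 peaks against 7 in random lists, adjusted permutation p = 0.0533) and without matching (adjusted p = 0.0655, range over all alternatives 0.0041 to 0.0655).

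The other kidney lists did not pass. Podocyte genes had a median of 9.67% against 4.78% (adjusted p = 0.116, permutation test), with Nes (35.7%, 32.6% ± 1.67 in the replicates), Lmx1b (35.3%, 30.4% ± 2.66) and Foxc2 (32.5%, 26.9% ± 5.31, all SD, n = 2) highest and Thsd7a lowest (1.25%). Endothelial genes had 11.3% (9.20% ± 2.73 in the replicates, SD, n = 2) against 5.55% (adjusted permutation p = 0.0858). Notch1 (51.2%, 47.5% ± 5.35), Eng (39.4%, 34.7% ± 5.23) and Plvap (37.8%, 31.9% ± 5.94, all SD, n = 2) were highest and Emcn (1.12%) lowest. With the mean in place of the median both lists passed (13.7% against 8.14%, adjusted permutation p = 0.0416, and 16.9% against 8.60%, adjusted p = 0.0022). The range of adjusted p over all alternatives was 0.0416 to 0.302 for podocyte and 0.0022 to 0.161 for endothelial genes, which also passed over the gene body ±5 kb. Proximal tubule genes, many of which encode transporters of the mature tubule, had 7.5% against 5.59% (adjusted permutation p = 0.495), from Hnf1a at 27.7% (24.3% ± 4.82) and Ass1 at 22.3% (19.6% ± 4.98, both SD, n = 2) to Slc5a12 at 0%. Genes of the loop of Henle and distal tubule had 4.85% against 4.48% (adjusted permutation p = 0.827), with Clcnkb (20.4%, 16.8% ± 6.03), Pou3f3 (15.1%, 11.5% ± 2.15) and Kcnj1 (13.6%, 11.6% ± 3.47, all SD, n = 2) highest.

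Among lists for other cells and organs, olfactory receptor genes alone passed, with a lower coverage than random genes. Their median was 0% against 7.52% (adjusted p = 0.0012, permutation test), and 969 of 1134 had no covered base. Macrophage genes had a median of 9.65% against 5.85% (adjusted permutation p = 0.348), with Fcer1g (25.6%, 21.2% ± 3.74, SD, n = 2) highest and Ptprc (0.409%) lowest. Erythroid genes had 2.72% against 6.86% (adjusted permutation p = 0.160). Their highest member was Nfe2 (36.1%, 30.7% ± 0.551 in the replicates, SD, n = 2). Adrenal cortex genes had 6.04% against 5.06% (adjusted permutation p = 0.805), gonad and germ line genes 6.71% against 5.22% (0.656), hepatocyte genes 3.02% against 5.56% (0.348), and neuron genes 5.97% against 3.61% (0.348). Striated muscle genes had 10% against 5.23% (0.160), epidermis genes 1.79% against 5.79% (0.160) and housekeeping genes 11.9% against 6.21% (0.0926). Hepatocyte and epidermis genes passed as lower by the mean (3.93% against 8.43%, adjusted permutation p = 0.0416, and 3.36% against 9.28%, 0.0192), and neuron genes as higher over the gene body ±5 kb (19.6% against 4.34%, 0.0022). Adjusted p over all alternatives ranged from 0.0416 to 0.575 for hepatocyte, 0.0192 to 0.319 for epidermis and 0.0022 to 0.925 for neuron genes. No test compared the kidney lists with the housekeeping list or with the other lists. A window can hold peaks of neighbouring genes. On simulated lists of 20 genes a doubling of coverage gave an unadjusted permutation p under 0.05 in 54.3% of lists. The adjusted p used for the calls is stricter, so lists that did not pass can still differ.

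**Figure D3:**
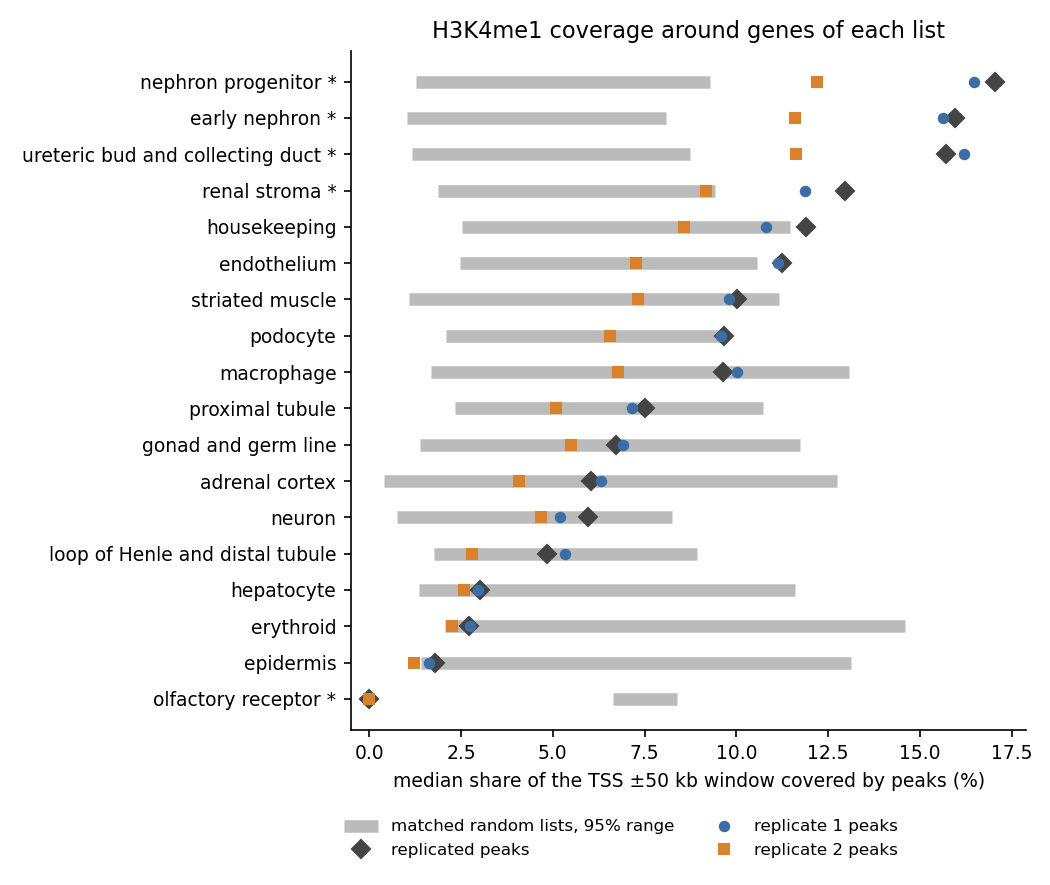
Median share of the TSS ±50 kb window covered by H3K4me1 peaks (x axis, %) for the genes of each of 18 lists (y axis). Diamonds are replicated peaks, circles replicate 1 and squares replicate 2, grey bars are the 95% range of random lists matched on gene length and density and apply to the diamonds, and an asterisk marks an adjusted p under 0.05. Nephron progenitor, early nephron, ureteric bud and stroma lists lie above the grey bars at 13.0% to 17%, and the olfactory receptors lie at 0%. The housekeeping (11.9%) and endothelial (11.3%) lists also lie above their bars but did not pass after adjustment.

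Along the 4 Hox clusters, whose order follows the body axis, the median over all clusters was highest in the anterior groups, but single clusters differed. The median covered share of the gene body ±2 kb was 79.6% for the 23 genes of paralogue groups 1 to 8 (68.4% ± 4.09 in the replicates, SD, n = 2), 59.6% for the 10 genes of groups 9 to 11 (54.1% ± 13.5, SD, n = 2) and 31.6% for the 6 genes of groups 12 and 13 (28.2% ± 8.52, SD, n = 2). No test was run. Between groups 1 to 8 and 12 to 13 the replicate means lay further apart than either SD, and the gap between groups 1 to 8 and 9 to 11 was close to the SD of the latter. Each SD also holds a shift shared by the groups, since replicate 2 was lower in every group. Groups 1 to 8 and 9 to 11 had medians of 71.3% and 63.6% in replicate 1, and 65.5% and 44.6% in replicate 2. By cluster, the medians of groups 1 to 8, 9 to 11 and 12 to 13 were 92.2%, 40.4% and 25.3% in Hoxa, 64.6%, 95.3% and 21.7% in Hoxb, 82.6%, 71% and 28.5% in Hoxc, and 63.7%, 55.2% and 70.6% in Hoxd, from 1 to 8 genes each. The Hoxa and Hoxc clusters thus followed the pooled order and the Hoxb and Hoxd clusters did not. The most anterior genes, Hoxd1 (36%), Hoxa1 (52%) and Hoxb1 (59.6%), lay no higher than the median of groups 9 to 11. Hoxb3 (97.4%), Hoxa6 (97.2%) and Hoxa5 (96%) were covered almost throughout. Hoxc13 (19%), Hoxb13 (21.7%) and Hoxa13 (25.3%) were among the lowest. Exceptions were Hoxd12 at 94.4% (88.4% ± 0.961), Hoxb9 at 95.3% (93.2% ± 3.49) and Hoxa9 at 19% (17.3% ± 8.43, all SD, n = 2). Among the group 11 genes, which are needed for kidney formation, Hoxc11 had 71% (60.8% ± 10.9), Hoxd11 48.4% (34.3% ± 12.9) and Hoxa11 45.9% (41.7% ± 14.9, all SD, n = 2). Padded gene bodies of neighbouring Hox genes overlap, so their values are not independent.

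**Figure D4:**
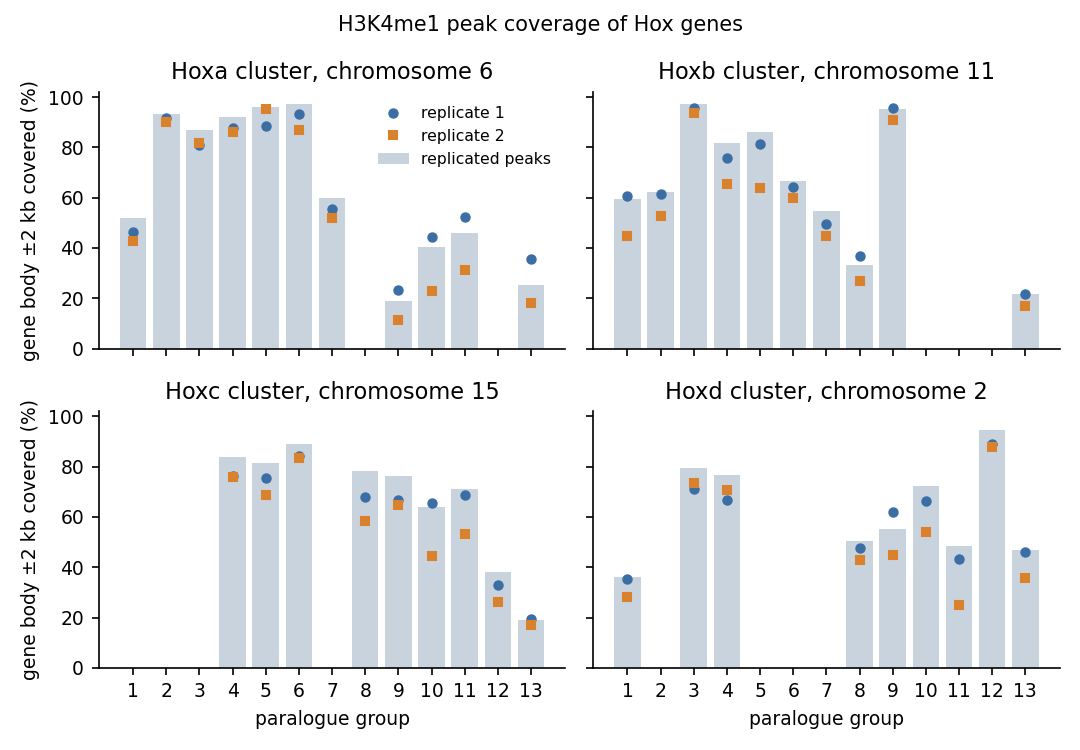
Share of each Hox gene body ±2 kb covered by H3K4me1 peaks (y axis, %) by paralogue group (x axis) in the 4 clusters; bars are replicated peaks, circles replicate 1 and squares replicate 2. The median over all clusters is 79.6% in groups 1 to 8 and 31.6% in groups 12 and 13, while Hoxd1 (36%) and Hoxa9 (19%) lie low and Hoxd12 (94.4%) lies high.

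With replicate 1 reduced to its 173543 strongest peaks, the full number of replicate 2, it covered more than replicate 2 around the genes of 4 kidney lists. The excess of replicate 1 over replicate 2 had a median of 2.96 percentage points for ureteric bud and collecting duct genes (19 of 21 higher in replicate 1), against 0.329 in matched random lists. It was 1.80 points for nephron progenitor genes (18 of 20), 1.59 for early nephron genes (18 of 18) and 1.79 for endothelial genes (18 of 20). Adjusted p was 0.0018 for the first and 0.0151 for each of the other 3 (two-sided permutation test, Benjamini-Hochberg over 18 lists). Olfactory receptor genes passed as lower (0 points against 0.639, adjusted permutation p = 0.0018), but with 969 of 1134 genes uncovered by replicated peaks their median says nothing about the replicates. Among ureteric bud genes the excess was largest at Wnt11 (32.7% against 26.4%) and Aqp2, the water channel of the collecting duct (17.8% against 11.8%), and Etv5 went the other way (11.2% against 11.6%). In the other lists it was largest at Lfng (39.8% against 30.3%), Uncx (29.3% against 22.8%) and Plvap (34.3% against 27.7%), and Itga8 had less in replicate 1 (2.36% against 4.63%).

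The other 13 lists did not pass. Their medians were 0.760 points for podocyte, 0.713 for renal stroma, 1.11 for proximal tubule, 0.850 for loop of Henle and distal tubule, 1.33 for macrophage, 0 for erythroid, 0.959 for adrenal cortex, 0.796 for gonad and germ line, 0.0445 for hepatocyte, 0.954 for neuron, 1.01 for striated muscle, 0.0375 for epidermis and 1.73 for housekeeping genes, with adjusted p from 0.0648 to 0.447 (permutation test). With equal numbers of peaks replicate 1 still covered more of the genome (105 Mb against 91.3 Mb). When replicate 1 was reduced instead to the 128395 peaks that cover as much as replicate 2, an alternative chosen after seeing the data, the ureteric bud list alone passed (0.982 points, adjusted p = 0.0036, permutation test). Against random genes of the same mean coverage, also chosen after seeing the data, no list passed at an adjusted p under 0.05, and the ureteric bud list alone had an unadjusted p under 0.05 (0.0192, adjusted 0.346).

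Of 19 consensus motifs, 14 were found in more distal peaks than flanks, and no test compared motifs of kidney factors with the others. Motif shares are unweighted means over 20 chromosomes, and each ratio is of these means. There were 100283 replicated peaks over 2.5 kb from any TSS and 134512 flanks. The HNF1 consensus, bound by the tubule regulators HNF1A and HNF1B, was matched in 0.233% of peaks against 0.0786% of flanks (ratio 2.97, higher on 19 of 20 chromosomes). The NFI consensus was found in 2.43% against 1.01% (ratio 2.42, 20 of 20), and the E-box bound by myogenic factors and other basic helix-loop-helix proteins in 32.7% against 19.8% (ratio 1.65, 20 of 20). The ETS consensus had a ratio of 1.47, REST 1.38, CREB 1.32 (higher on 14 of 20 chromosomes) and PAX2/8 1.25. The TEAD consensus was in 29.1% of peaks against 24.1% of flanks (ratio 1.21), the SIX-family consensus in 17% against 14.5% (1.18), FOX in 7.73% against 6.67% (1.16) and HOX/PBX in 4.84% against 4.19% (1.15). AP-1 (1.14), NEUROD (1.08) and SOX (1.06) had small excesses. These 14 motifs passed at an adjusted p of 0.0037 for CREB and 2.71e-05 or less for the others, and HOX9-13 passed as lower (27.9% against 34.8%, ratio 0.802, lower on 20 of 20 chromosomes, adjusted p = 1.46e-05, two-sided sign-flip permutation test). HNF4 (ratio 1.08, adjusted permutation p = 0.466), TCF/LEF (0.994, 0.515), GATA (1.01, 0.603) and CTCF (0.997, 0.942) did not pass. In replicate 1 peaks alone, HNF4 passed with a ratio of 1.07 (adjusted p = 0.0422, permutation test).

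Base composition changed part of this picture, since peaks were richer in GC than flanks (48.7% against 44.3%). Within bins of GC content HOX9-13 turned to a higher share in peaks (ratio 1.15, 20 of 20 chromosomes), TCF/LEF (1.2) and GATA (1.2) became higher, and the ratio rose to 5.54 for HNF1 and 1.67 for HOX/PBX. REST (1.05, adjusted permutation p = 0.117), CREB (1.05, 0.684) and NEUROD (0.988, 0.448) no longer passed, while the other 11 motifs kept a higher share in peaks. In regions of 200 bp CTCF (0.775) and TCF/LEF (0.959) passed as lower. Against other orders of the same letters, a comparison chosen after seeing the data, 0 of 19 motifs passed (lowest adjusted p = 0.0633, permutation test), and 8 had an unadjusted p under 0.05. Of those orders none reached the ratio of HNF1, NFI, FOX, TEAD or the E-box, and 1 reached that of ETS. HNF1, at 5.05 times the median of its other orders, and NFI, at 1.96 times, had the smallest p that their number of orders allows (permutation p = 0.0067). FOX (0.0111), TEAD (0.0333) and the E-box (0.0476), with fewer orders, were also at their smallest possible permutation p. Adjusted over 19 motifs, these became 0.0633 for HNF1, NFI and FOX, 0.106 for TEAD and 0.113 for the E-box. The count of 0 therefore does not count against these motifs. The ratio to the median of the other orders was 1.73 for HOX/PBX, 1.38 for the E-box (41 orders), 1.37 for FOX (179 orders), 1.26 for ETS and 1.16 for TEAD (59 orders).

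**Figure D5:**
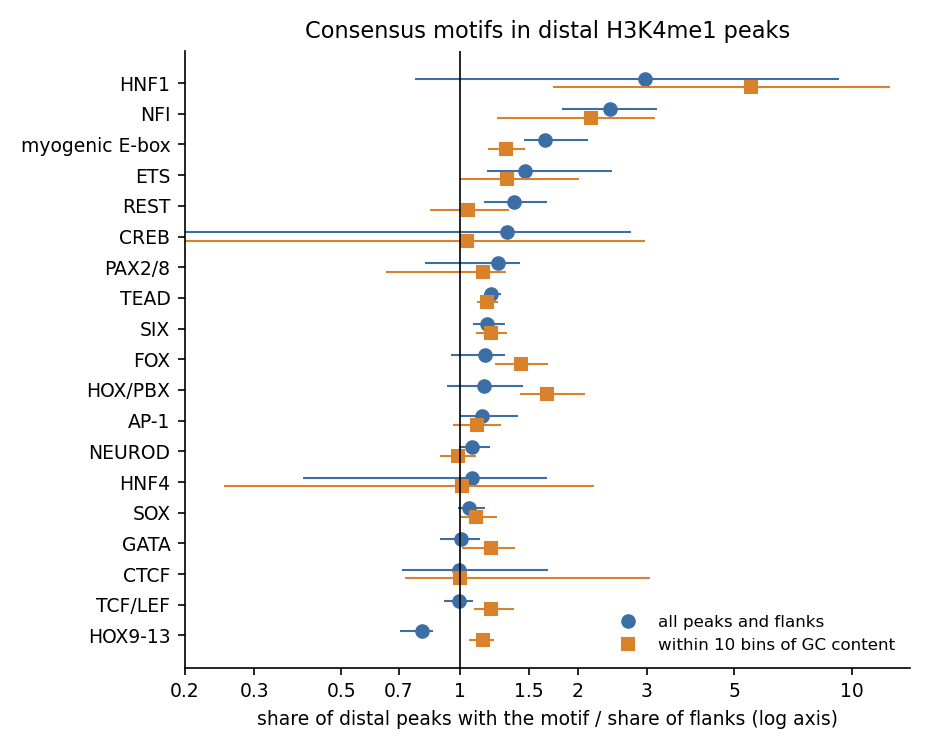
Ratio of the share of distal H3K4me1 peaks with a consensus motif to the share of flanking regions (x axis, log scale) for 19 motifs (y axis); circles are all peaks and flanks, squares are comparisons within 10 bins of GC content, and lines span the lowest and highest of 20 chromosomes, running off the left edge for CREB, whose lowest is 0. HNF1 stands highest at 2.97 and 5.54 within GC bins, and HOX9-13 moves from 0.802 to 1.15.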

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

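Overlap of peaks above shifted peaks held in 8 of 8 tests under 4 alternatives, between 47.7% and 67.9% for replicate 1 peaks and 72.2% and 84.4% for replicate 2 peaks. Shared length, which the rules for overlap of single peaks cannot change, was 49.8% at −log10 q of at least 5 and 53.3% with equal numbers of peaks, and the 4 genomic shares kept their direction and call in 20 of 20. The nephron progenitor, early nephron and ureteric bud lists passed as higher in 13 of 13 alternatives (adjusted p up to 0.0137, 0.018 and 0.0168), and the olfactory receptors as lower in 12 of 12 (up to 0.0036; random genes outside that list were not drawn). Of 272 values of named genes under 4 alternatives, 145 moved by less than the SD between replicates and 127 did not. The 127 include unchanged values of Sycp1, Myh1 and Dsg1a, which were at 0% in each replicate with an SD of 0. Of 68 values in each alternative, 62 were in the latter class without replicate 1, against 19 without replicate 2, 19 with pooled peaks and 27 at −log10 q of at least 5. The value without replicate 1 is that of replicate 2's own list, which is smaller, and the SD comes from the same 2 lists. These counts therefore do not measure dependence on replicate 1. The alternatives of equal covered length, matching on coverage, matching on chromosome class, flanks away from TSSs, permuted letters and start sites in each replicate were chosen after seeing the data. The lists hold no read counts, so how far depth limits the weak peaks is unknown. Where no cause is named, the cause was not tested.

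Stricter thresholds keep fewer peaks by construction. At −log10 q of at least 5 there remained 83857 replicate 1, 53494 replicate 2, 103640 pooled and 99951 replicated peaks, and at an enrichment of at least 4 there remained 40185, 37570, 32566 and 32564. Rank correlation was 0.492 at −log10 q of at least 5 and 0.613 by −log10 p. Leaving out each replicate in turn gave 13.9% to 20.6% at the TSS, Hox medians of 65.5% to 71.3% (groups 1 to 8), 44.6% to 63.6% (9 to 11) and 22.1% to 34.2% (12 and 13), and the order of the Hox groups held in both. At the start site, nephron progenitor (30% against 20%, adjusted permutation p = 0.602), ureteric bud (28.6% against 19%, 0.544) and renal stroma genes (30% against 15%, 0.402) lost their call without replicate 1, and early nephron (27.8% against 22.2%, 0.830) and neuron genes (55.6% against 27.8%, 0.0571) without replicate 2. Striated muscle genes, which never passed there, went from 25%, at the random median, to 18.75% against 25% without replicate 2. At −log10 q of at least 5 the median of groups 1 to 8 was 72.8%.

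Among gene lists, renal stroma lost its call by number of peaks (14.5 against 7, adjusted permutation p = 0.0533) and without matching (13.0% against 5.74%, 0.0655; the random median rose). By the mean, podocyte (13.7%), endothelium (16.9%), hepatocyte (3.93%) and epidermis (3.36%) passed, and over the gene body ±5 kb endothelium (17.5%) and neuron (19.6%) passed. Lists that never passed changed side of the random median: proximal tubule over the gene body (5.42% against 6.05%) and by the mean (8.56% against 8.61%), loop of Henle and distal tubule with a 100 kb window (4.22% against 4.58%), without matching (4.85% against 5.73%), with chromosome class (4.85% against 4.97%), by the mean (6.67% against 7.36%) and without replicate 1 (2.79% against 3.22%, but 5.33% against 4.32% without replicate 2), and adrenal cortex and gonad with a 20 kb window (4.55% against 5.59%, 5.49% against 6.08%) and over the gene body (4.73% against 6.48%, 1.69% against 5.79%).

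For the replicate difference, equal covered length ended the calls of nephron progenitor (0.504 points, adjusted permutation p = 0.109), early nephron (0.266, 0.223), endothelium (0.101, 0.643) and olfactory receptor genes (0, 1), and put podocyte (−0.321), proximal tubule (−0.0215) and housekeeping genes (−0.00950) below the random median. Hepatocyte genes, below it already, fell from 0.0445 to −0.141 (adjusted permutation p = 0.223). Matching on coverage leaves the medians as they are and moves the random median, to 1.77 for nephron progenitor (1.80, adjusted permutation p = 1), 1.72 for early nephron (1.59, 0.989), 1.11 for podocyte (0.760, 0.627), 1.80 for ureteric bud (2.96, 0.346), 1.32 for renal stroma (0.713, 0.604), 1.37 for endothelium (1.79, 0.627) and 0 for olfactory receptor genes (0, 1). At −log10 q of at least 5 podocyte (2.82, 0.0086) and renal stroma (2.40, 0.0384) passed and endothelium did not (2.42, 0.0607). A 100 kb window called macrophage (1.88), striated muscle (1.73) and, as lower, hepatocyte (−0.0508) genes, and the mean called hepatocyte genes as lower (0.165 against 1.03).

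Within GC bins 14 motifs were higher and 0 lower: HOX9-13 (1.15), TCF/LEF (1.2), NEUROD (0.988) and CTCF (1.00) changed side. In 200 bp regions 3 motifs were lower and GATA changed side (0.972). Against permuted letters 0 were higher and 0 lower, although no order reached HNF1, NFI, FOX, TEAD or the E-box. The permutation p of each was the smallest its number of orders allows (0.0067 for HNF1 and NFI, 0.0111 for FOX, 0.0333 for TEAD, 0.0476 for the E-box). Ratios to the permuted median were 5.05 for HNF1, 1.96 for NFI, 1.73 for HOX/PBX, 1.38 for the E-box, 1.37 for FOX, 1.18 for TCF/LEF, 1.12 for HOX9-13 and 0.935 for NEUROD. Some orders did reach AP-1 (ratio to the permuted median 1.18), PAX2/8 (1.14), REST (1.08), CREB (1.08) and SOX (1.02). GATA (0.998) and CTCF (1.04) changed side at −log10 q of at least 5, and GATA (0.995) and CTCF (1.04) with flanks away from TSSs. Leaving out each replicate in turn gave 0.992 to 1.01 for TCF/LEF and 0.989 to 1.02 for GATA.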

Other observations

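The tests of single TSSs by list, also in each replicate, of copy number alone on the X chromosome, of replicate coverage against random genes of the same mean coverage, and the use of the planned GC bins as a test of base composition for HOX9-13, were chosen only after the result they bear on had been seen, and the combined test of copy number and repeats only after its separate parts had been seen. Compared with random genes of the same CpG content, a replicated peak covered the TSS of 70% of 20 endothelial genes (random median 30%, adjusted p = 0.0018, two-sided permutation test), among them the vascular transcription factors Erg, Fli1, Sox17 and Sox18. Genes named here for their start sites were chosen after their values were seen. Genes of the loop of Henle and distal tubule, which did not pass over 50 kb, were covered at 12 of 20 TSSs (60% against 20%, adjusted permutation p = 0.0022), including the Irx1, Irx2 and Irx3 genes of the intermediate nephron and Umod, the uromodulin gene. Neuron genes were covered at 12 of 18 TSSs (66.7% against 27.8%, adjusted permutation p = 0.0027), including Neurod1, Neurog2, Olig2 and Isl1. Nephron progenitor (65% against 30%), renal stroma (65% against 25%), ureteric bud (61.9% against 23.8%) and early nephron genes (55.6% against 22.2%) passed too, with adjusted p of 0.0026 or less, and olfactory receptors were lower (0.176% against 7.32%, 0.0018). In each replicate alone, endothelial (75% and 55%) and loop and distal tubule genes (50% and 40%) passed as higher and olfactory receptors as lower. Nephron progenitor (60%), renal stroma (60%) and ureteric bud genes (61.9%) passed in replicate 1 but not in replicate 2, where they reached 30%, 30% and 28.6% (adjusted permutation p = 0.602, 0.402 and 0.544). Early nephron and neuron genes passed in replicate 2 (38.9% and 50%) but not in replicate 1 (27.8% and 55.6%, adjusted permutation p = 0.830 and 0.0571), so the TSS calls of these 5 lists held in 1 replicate each.

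The other lists did not pass at the TSS. Podocyte and proximal tubule genes were each covered at 9 of 20 (45% against 25%, adjusted permutation p = 0.109 and 0.132), with Nphs1, Nphs2 and Synpo of the podocyte slit diaphragm and cytoskeleton and the endocytic receptors Lrp2 and Cubn of the proximal tubule among those covered. Macrophage (1 of 16, Cd14) and hepatocyte genes (1 of 16, Apoh) lay below their random medians (6.25% against 18.75% and 25%). Erythroid (26.7% against 13.3%) and epidermis genes (31.25% against 25%) lay above theirs, and adrenal cortex (21.4%), gonad and germ line (20%) and striated muscle genes (25%) lay at theirs. Housekeeping genes were covered at 3 of 22 TSSs (13.6% against 22.7%, adjusted permutation p = 0.654). No peak of any list lay on the Y chromosome.

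The X chromosome held 975 replicated peaks, 5.70 per Mb, where autosomes held 45.7 to 91.3 per Mb, and its median enrichment was 2.89. Gene length and gene density did not account for the few X peaks. The median window coverage of 948 X genes was 0 times that of autosomal genes matched on both (ratio of means 0.106, 95% interval 0.0911 to 0.121). The kinds of genes that X holds were not matched. Repeat and base content alone did not account for the few X peaks either. Matching on them lowered the autosomal density from 62.9 to 17.8 peaks per Mb of windows. X, at 6.27, still had 0.351 times (0.287 to 0.416) the matched peaks. If enrichment were proportional to copy number, an even mix of sexes would scale it by 0.75 on X. What the enrichment is relative to is not given in the sources used here, so this is an assumption. The highest factor that gave the X density was 0.565 (0.514 to 0.588 over the minima tried). Those bounds reflect the number of X peaks only. Against single autosomes the factor ranged from 0.471 to 0.655, which is also below 0.75. Copy number together with repeat and base content cannot be told apart from a further deficit, since the factor against matched windows was 0.719 (bounds 0.603 to 0.780) at its highest and 0.707 at its lowest over 4 minima, with upper bounds of 0.749 to 0.780 on both sides of 0.75, and a candidate explanation is that these combined with a calling threshold. The ratio of males to females in the pools, on which the assumed 0.75 depends, is not given in the sources used here, and no biological explanation was tested.

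Replicate 1 exceeded replicate 2 at 4 kidney lists, by 1.59 to 2.96 percentage points. Wider coverage of replicate 1 in proportion to the level is a candidate explanation, since 0 of the 4 lists passed against random genes of the same mean coverage, although ureteric bud genes kept an unadjusted p of 0.0192 and passed at equal covered length (0.982 points, adjusted permutation p = 0.0036). Other organs' tissue in replicate 2 would lower replicate 1 minus replicate 2 at the lists of other organs; 4 of the 6 lists lay above the random median and 0 passed as lower, although hepatocyte genes did with a 100 kb window (−0.0508, adjusted permutation p = 0.0012) and by the mean (0.165 against 1.03, 0.0234). That outcome had been set beforehand to count against this explanation, but 4 of 6 is within what chance gives, so the rule was tightened after the value was seen and the explanation stays open. Depth and tissue composition of the pools were not measured, the calls of replicate 1 drew on 1 more file, whose role is not given, and no biological explanation was tested.

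The HOX9-13 consensus, which is rich in A and T, was found in fewer distal peaks than flanks on 20 of 20 chromosomes (ratio 0.802). Base composition of the motif may account for the deficit, since within bins of GC content the ratio was 1.15 (1.06 to 1.22 over the chromosomes) and peaks had a GC content of 48.7% against 44.3% in flanks. The excess within bins was seen on 20 of 20 chromosomes, but the consensus did not pass against other orders of its own letters (ratio to their median 1.12, adjusted permutation p = 0.113). No motif passed that comparison, and 205 of 209 orders lay at or below the ratio of HOX9-13 (unadjusted permutation p = 0.0476). Whether a HOX factor binds these sites was not measured, and no biological explanation was tested.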
